A study of Rattus norvegicus with 209 samples.

How the data were processed

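Lung RNA of male SD rats was measured on Affymetrix rat arrays. Per the labels' protocols, total RNA was extracted with Trizol and turned into biotinylated cRNA. The deposited values are intensity signals that, per the submitters' processing notes, were made with MAS5, with no version given. Their mean after leaving out 2% of probe sets at each end lay between 150.1 and 150.3 on every array, so the authors had scaled each array to a common level. Detection calls and raw image files were not used here.

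Groups were taken from the labels: smoke or control on 12 days, and a cessation pair on day 238. Of 209 arrays, 1 was left out of all comparisons because its labels conflict, the title naming it control and the description smoke on day 14. The others formed 26 groups of 7 to 9 arrays. The number of arrays limits the precision. The replicate numbers of the labels were tested for pairing by correlating the residuals of equally numbered smoke and control arrays. On day 3 all 8 pairs correlated above 0.1, with a mean of 0.27 and a lowest value of 0.16, and with replicate number as a block 458 probe sets differed on that day against 408 without.

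Values were transformed as log2(value + 2.4), the constant being the 10th percentile of all values; folds on this scale understate the change of genes with low signals. Of 8799 probe sets, 59 control probe sets were set aside, and the 30% of the others with the lowest mean over all arrays (2622) were left out, which left 6118. Of all probe sets 7018 carry 1 gene symbol, 308 several and 1473 none listed. Genes were represented by the probe set with the highest mean, for 3597 genes.

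R 4.3.3 with limma 3.58.1 fitted 1 mean per group with a shared spread (182 residual degrees of freedom). Contrasts were smoke minus control on each day, the unweighted mean of these over 12 days, and an F test that they are equal. The mean of days 112, 182 and 238 minus that of days 1, 3 and 5 was taken for the smoke effect and for the controls. On day 238 the contrasts were smoke minus control after cessation, the latter minus the difference under continuing exposure, and the cessation controls minus the other controls. Tests were two-sided, with Benjamini-Hochberg adjustment over the 6118 probe sets and a threshold of 0.05. Errors of log2 differences are standard errors of the fit.

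Lists of genes for pathways, cell types and other tissues (41 lists) were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation. The ciliated cell list, with 3 measured genes, fell under the minimum of 5 and was not tested, which left 40. Genes called on day 182 were followed on day 238 by the median of their signed differences, with percentile intervals from 1000 resamples of animals within groups. Figures were drawn with matplotlib 3.10.9.

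The tests, gene lists and rules for naming genes were chosen before the data were examined. Named for the average difference were the 15 largest and 12 most negative genes with the sign of the average on at least 10 of 12 days. Named on each day were the 3 largest and 2 most negative, for the F test the 5 largest, and for the late minus early difference the 10 largest and 10 most negative. After cessation the 10 largest and 5 most negative were named, for cessation minus continuing exposure the 5 largest in each direction, and for the controls over time the 8 largest in each direction. The 3 largest in each direction were to be named for the controls of day 238. Members of lists were named from those with the smallest p, and Cyp1a1, Nqo1, Scgb1a1 and Mmp12 in every comparison.

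Alternatives were quantile normalization, centring each array on its median, a constant 4 times smaller or larger, no filter, a filter leaving out the lowest 50% of probe sets, only the groups of the comparison, a trended and robust variance model, array weights, the 3' over 5' ratio of control probe sets as a covariate, and replicate number as a block. Leaving out 4 arrays with a median correlation to all others under 0.91, leaving out day 182 or day 21, and centring for the gene lists and for the followed genes were added after seeing the data.

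The methods were tested on simulated data. For smoke against control on day 84 the fit recovered 60% of changes of 0.5 log2 and 92% of changes of 1, with 7 false calls among 6118. For the average difference it recovered 85% of changes of 0.25. For smoke against control after cessation it recovered 91% of changes of 1, with 12 false calls. Camera called the shifted macrophage list, and with it 5 of the 39 other lists at the preset and 3 of 39 at the estimated correlation. Some of these other lists share genes with the shifted list. The signed median recovered 0.98 and 0.50 where 1 and 0.5 were set.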

Results

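Gene expression was measured on 209 arrays of lung tissue from male SD rats, each array reporting 8799 probe sets. The labels place all but 1 of them in 26 groups: smoke and control animals on each of 12 days between day 1 and day 238, and a separate pair of groups on day 238 named cessation. Most groups held 8 arrays. The smoke group of day 112 and the control group of day 14 held 7, and the smoke group of day 182 and the control group of day 3 held 9. The labels give neither the smoke dose nor the day on which exposure ended in the cessation group. The number of arrays per group limits the precision of every value.

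The comparisons within each day asked how the lung differed between smoke and control animals after that length of exposure. The response was present on day 1, when Cyp1a1, a cytochrome P450 that oxidises polycyclic aromatic hydrocarbons, had a mean signal of 1040 ± 173 in the smoke group against 4.18 ± 3.16 in the control group (SD, n = 8 in each). On the scale with the added constant this was a log2 difference of 7.40 ± 0.19 (SE), or 169-fold, with an adjusted p of 4e-88. Aldh3a1, an aldehyde dehydrogenase, rose by 4.82 ± 0.16 on day 1 with an adjusted p of 5.4e-70, and Cyp1b1, a related P450, rose by 3.64 ± 0.24 with an adjusted p of 1.7e-31. On day 238 the differences were 8.10 ± 0.19 for Cyp1a1, 4.36 ± 0.24 for Cyp1b1 and 4.05 ± 0.16 for Aldh3a1. Nqo1, a quinone reductase, rose by 2.64 ± 0.15 on day 1 and by 1.51 ± 0.15 on day 238. Lcn2, which binds bacterial iron carriers, was among the 3 largest differences on day 28 only, at 4.05 ± 0.41 with an adjusted p of 2.9e-16.

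Among the genes that fell, Cyp2a3, a P450 of the airway epithelium, stood at -1.63 ± 0.40 on day 1, -1.85 ± 0.39 on day 3, -1.87 ± 0.40 on day 42 and -1.84 ± 0.40 on day 84. Kcnk3, a potassium channel, stood at -1.13 ± 0.32 on day 1, and its adjusted p of 0.015 became 0.058 when arrays were weighted by quality. Bmal1, a transcription factor of the circadian clock, stood at -1.71 ± 0.35 on day 5 and -1.72 ± 0.36 on day 14, and Hsd11b2, which inactivates glucocorticoids, at -1.60 ± 0.27 and -1.52 ± 0.28 on those days. Cyp26b1, which degrades retinoic acid, stood at -1.85 ± 0.33 and the glutamate receptor Grm3 at -1.54 ± 0.26 on day 28, and Prune2 at -1.48 ± 0.20 on day 56. Dlk1, a membrane protein of the Notch ligand family, was among the most negative differences on day 3 and from day 42 on. It stood at -1.40 ± 0.33 on day 3, with an adjusted p of 0.0019 that became 0.061 with the groups of the day alone, and at -2.76 ± 0.36 on day 112, and Cdh22, a cadherin, stood at -2.54 ± 0.41 on that day. The muscle genes Ckm and Myh7 had the most negative differences on day 21, at -2.91 ± 0.74 with an adjusted p of 0.0023 and -2.63 ± 0.89 with an adjusted p of 0.033. All 8 smoke arrays lay below the control mean for Ckm and 7 of 8 for Myh7, and 5 of 8 lay below every control array for either gene. For Myh7 the adjusted p was 0.076 with the day 21 groups alone and 0.11 with array weights. The secretory protein of club cells, Scgb1a1, passed the threshold on day 182, at -0.23 ± 0.08 with an adjusted p of 0.018, and not with arrays centred on the median, at -0.11 with an adjusted p of 0.49. Scgb1a1 also passed on day 238 with quantile normalization, at -0.21 with an adjusted p of 0.046, and with array weights, at -0.18 with an adjusted p of 0.038.

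By limma at an adjusted p under 0.05, 279 probe sets differed on day 1, 408 on day 3, 313 on day 5 and 519 on day 14. On later days 789 differed on day 21, 667 on day 28, 715 on day 42, 1152 on day 56, 1803 on day 84, 1477 on day 112, 1821 on day 182 and 1049 on day 238. From day 84 to day 182 most of these were lower in smoke lungs: 549 were higher and 1254 lower on day 84, 494 and 983 on day 112, and 594 and 1227 on day 182. That split depended on the scaling of the arrays. With arrays centred on the median, 954 were higher and 487 lower on day 84, 750 and 391 on day 112, and 813 and 597 on day 182. With quantile normalization the numbers were 674 and 812, 580 and 659, and 660 and 831. Centring moved the median log2 difference of all tested probe sets from -0.159 to 0.0337 on day 84, from -0.133 to 0.0269 on day 112, from -0.126 to 5.78e-04 on day 182 and from -0.0851 to 0.0514 on day 14. Quantile normalization moved it to -0.0568 on day 84. On day 3 the split was 185 higher and 223 lower, against 234 and 179 with quantile normalization and 228 and 96 with centring. On day 14 it was 251 higher and 268 lower, against 284 and 168 with quantile normalization and 381 and 91 with centring. With centring it changed from 408 and 381 to 451 and 242 on day 21, and from 417 and 632 to 430 and 426 on day 238. With the groups of the day alone in the fit, 241 probe sets differed on day 3, 186 on day 5, 251 on day 21 and 434 on day 28. With array weights, 510 differed on day 21 and 1696 on day 238. Of the 789 calls of day 21, 529 were kept without the 4 arrays of low correlation.

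**Figure D1:**
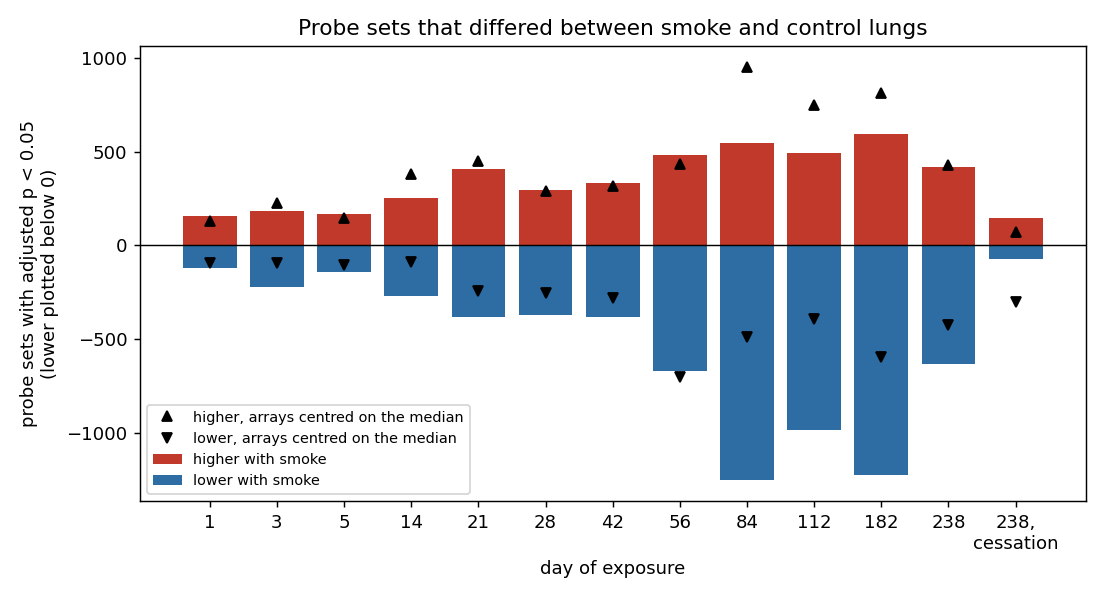
Number of probe sets with an adjusted p under 0.05 (vertical axis, lower ones below 0) by day of exposure, with bars for the deposited scaling and triangles for arrays centred on the median. On day 84 the bars show 549 higher and 1254 lower, and the triangles 954 higher and 487 lower.

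Over the whole course 17 genes were higher on all 12 days, among them Cyp1a1, Nqo1, Aldh3a1, Cyp1b1, Ggt1, Hmox1, Txnrd1, Gsta3 and the transcription factor Nfe2l2 (NRF2), together with Lgals3, Fabp5, Chia, Per2, Enpp2, Atp1b1, Plaur and Il1r2. The 9 genes lower on all 12 days were Cyp2f4, Pola2, Fzd1, Gja4, G0s2, Prune2, Pcp4l1, Car4 and Prkcb. These names follow from the count and not from the rule for named genes. Of 2224 genes that differed on at least 1 day, 383 did so in 1 direction on 6 or more days, and 56 were higher on at least 1 day and lower on at least 1 other.

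The mean of the 12 daily differences asked which genes differed with smoke exposure on average over the course. A gene that changed only on some of the days can also pass it. Cyp1a1 rose by 7.64 ± 0.05 (SE, 200-fold, adjusted p = 1.3e-186), Aldh3a1 by 4.24 ± 0.05 and Cyp1b1 by 3.90 ± 0.07, each higher on all 12 days. The control signal of Cyp1a1 lay near the constant of 2.4 added before the logarithm, so its fold depends on it: the log2 difference was 8.28 with a constant 4 times smaller and 6.41 with one 4 times larger. Ggt1, which splits glutathione outside the cell, rose by 2.85 ± 0.07 (adjusted p = 2e-90), Nqo1 by 2.03 ± 0.04 (adjusted p = 3.5e-103) and the haem oxygenase Hmox1 by 1.61 ± 0.05 (adjusted p = 2e-70). Lcn2 rose by 2.57 ± 0.12, the chitinase Chia by 2.56 ± 0.06, the macrophage elastase Mmp12 by 2.35 ± 0.10 (adjusted p = 1.4e-57, positive on 11 of 12 days), osteopontin (Spp1) by 1.91 ± 0.15, the calprotectin subunit S100a9 by 1.76 ± 0.08 and the chemokine Ccl3 by 1.60 ± 0.06. The others of the 15 largest were C2cd4b at 1.77 ± 0.09, Pdzk1ip1 at 1.49 ± 0.11 and C4bpa at 1.49 ± 0.05. The most negative means were -1.52 ± 0.10 for Dlk1 (adjusted p = 5.3e-33, negative on 11 of 12 days), -1.29 ± 0.09 for Cyp26b1 and -1.21 ± 0.12 for Cyp2a3. Also lower were Prune2 at -1.16 ± 0.06, Tac1, the precursor of substance P, at -1.11 ± 0.06, Pcp4l1 at -1.08 ± 0.05 and Grm3 at -1.07 ± 0.07. These were followed by Hsd11b2 at -1.03 ± 0.08, Bmal1 at -1.01 ± 0.10, the receptor Vipr2 at -0.99 ± 0.06, Cyp2f4 at -0.97 ± 0.06 and Cdh22 at -0.96 ± 0.12. Scgb1a1 stood at -0.10 ± 0.02 with an adjusted p of 0.00014, negative on all 12 days, and at -0.03 with an adjusted p of 0.35 with arrays centred on the median.

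In this comparison 3430 of 6118 probe sets passed the threshold, 1067 higher and 2363 lower, and they stand for 2111 genes. Only 169 of those higher and 115 of those lower differed by 1.5-fold or more. With arrays centred on the median 1510 were higher and 1477 lower. Of the 2111 genes, 599 had the sign of their average on all 12 days.

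**Figure D2:**
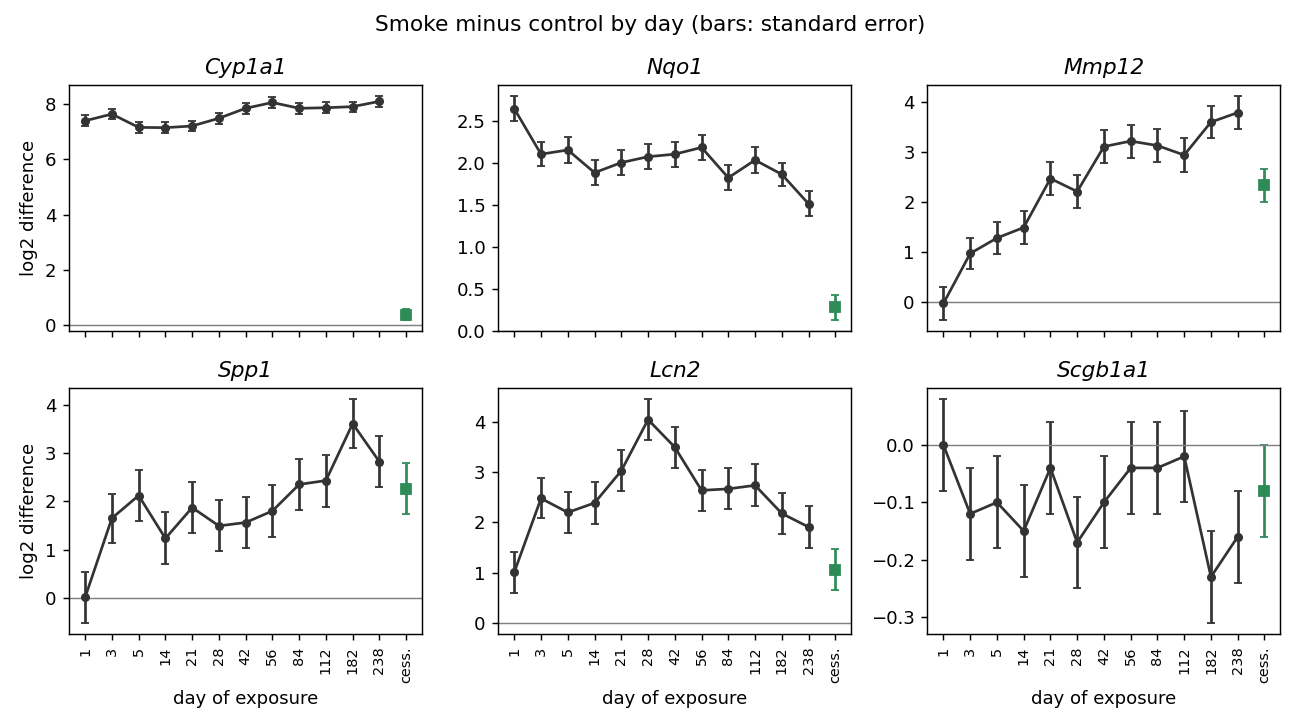
Log2 difference between smoke and control groups (vertical axis) by day of exposure for 6 genes, as points with bars of 1 standard error, with the cessation groups of day 238 as a green square. Cyp1a1 lay between 7.15 and 8.10 on the exposure days and at 0.39 after cessation, and Mmp12 at -0.03 on day 1, 3.79 on day 238 and 2.34 after cessation.

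Of 40 gene lists tested with camera on the average difference, 23 passed the threshold, 15 of them higher and 8 lower against the other genes, and 14 also did so with an estimated correlation. The aryl hydrocarbon receptor battery had 4 of 6 measured members higher, 1 lower and 1 not called (adjusted p = 2.7e-17); Cyp1a1, Aldh3a1, Cyp1b1 and Nqo1 rose, and the receptor Ahr itself fell by 0.29 ± 0.11. In the NRF2 and glutathione list 20 of 28 members rose, 4 fell and 4 did not pass (adjusted p = 2.7e-17), with Gsta3 at 1.23 ± 0.04 and the thioredoxin reductase Txnrd1 at 1.01 ± 0.04. Adjusted over the list alone, 21 rose and 4 fell. The list of metallothioneins and metal handling had 8 of 10 members higher and 0 lower (adjusted p = 8.1e-07), among them Lcn2, the iron importer Slc11a2 at 0.68 ± 0.03 and the transferrin receptor Tfrc at 0.63 ± 0.07. Of 24 other cytochromes P450 and monooxygenases, 14 fell, 2 rose and 8 did not pass, with Cyp4b1 at -0.81 ± 0.03 and Fmo1 at -0.83 ± 0.04 (adjusted p = 0.025). That call was lost at an adjusted p = 0.16 with an estimated correlation. Adjusted over the list alone, the counts in these lists other than that of NRF2 were unchanged.

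Of 21 measured macrophage markers, 16 rose, 0 fell and 5 did not pass, and 17 rose adjusted over the list alone (adjusted p of the list 1.6e-20). Fabp5, a fatty acid carrier, rose by 1.12 ± 0.03, the galectin Lgals3 by 1.16 ± 0.04, and the cathepsins Ctsk and Ctsd by 1.42 ± 0.06 and 1.11 ± 0.03. The macrophage list shares 15 of its 21 measured genes with other lists. The lysosome list, which also holds Ctsk and Ctsd, had 21 of 27 members higher and 0 lower (adjusted p = 5e-17), with the acid phosphatase Acp5 at 0.81 ± 0.04. In the list of proteases and inhibitors 15 of 32 rose and 8 fell (adjusted p = 0.0002), with Plaur at 0.97 ± 0.04. Chemokines and cytokines had 13 of 23 members higher and 6 lower (adjusted p = 0.00019), among them Ccl2 at 1.24 ± 0.06 and Cxcl6 at 1.42 ± 0.08. Of 9 neutrophil markers 4 rose, Lcn2, S100a9, S100a8 and the receptor Cxcr1, and 1 fell (adjusted p = 0.00086). Complement and acute phase genes had 12 of 18 members higher and 3 lower (adjusted p = 9.5e-05), with C1qb at 0.79 ± 0.03 and C3 at 1.38 ± 0.06. Adjusted over the list alone, the counts of these 5 lists were unchanged.

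Lymphocyte markers went the other way: of 22 markers of T cells and natural killer cells 21 fell and 0 rose (adjusted p = 1.9e-07), with the granzyme Gzmm at -0.89 ± 0.06, Klrb1a at -0.70 ± 0.05 and Klrd1 at -0.74 ± 0.06. All 6 measured genes of the thymus and lymph node list fell (adjusted p = 0.0025, and adjusted p = 0.059 with an estimated correlation), with Cd8a at -0.92 ± 0.08. Of 15 interferon response genes 13 fell and 0 rose, with Gbp2 at -0.63 ± 0.06 (adjusted p = 0.00097, and adjusted p = 0.17 with an estimated correlation). Of 10 markers of mast cells and eosinophils 8 fell and 0 rose, with Kit at -0.84 ± 0.06 (adjusted p = 0.019, and adjusted p = 0.17 with an estimated correlation). All 9 alveolar type 1 markers fell (adjusted p = 9.5e-05), among them Cyp4b1, Igfbp2 at -0.56 ± 0.05 and Pdpn at -0.33 ± 0.03. Of 16 alveolar type 2 and surfactant genes 11 rose and 1 fell (adjusted p = 6.4e-06), led by Chia, Ctsh at 0.39 ± 0.03 and the fatty acid synthase Fasn at 0.57 ± 0.04; 2 fell adjusted over the list alone. Of 38 extracellular matrix genes 25 fell and 5 rose, with Col5a2 at -0.42 ± 0.03 (adjusted p = 0.025, and adjusted p = 0.078 with an estimated correlation). Of 13 smooth muscle genes 12 fell and 0 rose, with Tpm1 at -0.28 ± 0.03 (adjusted p = 0.011, and adjusted p = 0.16 with an estimated correlation). Adjusted over the list alone, the counts of the lists of falling genes were unchanged.

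A further 5 lists passed. The glucocorticoid response list had 10 of 19 members higher and 5 lower (adjusted p = 0.00067), with the decoy receptor Il1r2 at 1.14 ± 0.05. In the circadian clock list 6 of 11 rose and 1 fell (adjusted p = 0.004, and adjusted p = 0.064 with an estimated correlation): Bhlhe41 and Per2, repressors of the clock, rose by 1.36 ± 0.05 and 1.23 ± 0.07, while Bmal1, an activator, fell. Hypoxia and glycolysis genes had 11 of 23 higher and 7 lower (adjusted p = 0.012), with the glucose transporter Slc2a1 at 0.81 ± 0.05. Lipid uptake, storage and oxidation genes had 13 of 29 higher and 6 lower, with Fabp5 at 1.12 ± 0.03 and the lipase Lipe at -0.67 ± 0.06 (adjusted p = 0.011, and adjusted p = 0.064 with an estimated correlation); 14 were higher adjusted over the list alone. Immediate early genes had 8 of 27 higher and 8 lower, with Ier3 at 0.76 ± 0.05 and Nr4a1 at -0.54 ± 0.07 (adjusted p = 0.034, and adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, the counts of the other 4 lists were unchanged.

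The remaining 17 lists did not pass, with adjusted p from 0.069 for nerve and neuroendocrine genes to 0.93 for sterol and fatty acid synthesis. They include club cell markers, of which 6 rose and 5 fell among 13, mucous and serous secretion, B cells and plasma cells, antigen presentation, endothelial cells, cell cycle, p53, heat shock, oxidative phosphorylation, ribosomal proteins, red blood cells, mesothelium, and heart muscle, skeletal muscle and fat. The antigen presentation list had a median of -0.06 and a mean of -0.01 while camera placed it above the other genes, and its 9 higher and 10 lower members became 9 and 11 adjusted over the list alone. In all 23 lists that passed, the median kept its sign under both other scalings. In a simulation with only the macrophage list shifted, camera also called 5 of the 39 other lists, and 3 of 39 with an estimated correlation. Of the 21 shifted genes 15 also stand in other lists, so these calls need not all be false. When smoke and control labels were exchanged at random within each day, camera at the preset correlation still called a median of 4 lists. The highest number there was 19, so camera at that setting also called lists where no difference by smoke was left. Single lists with a modest adjusted p call for caution, and whether counts of members are more reliable was not tested.

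**Figure D3:**
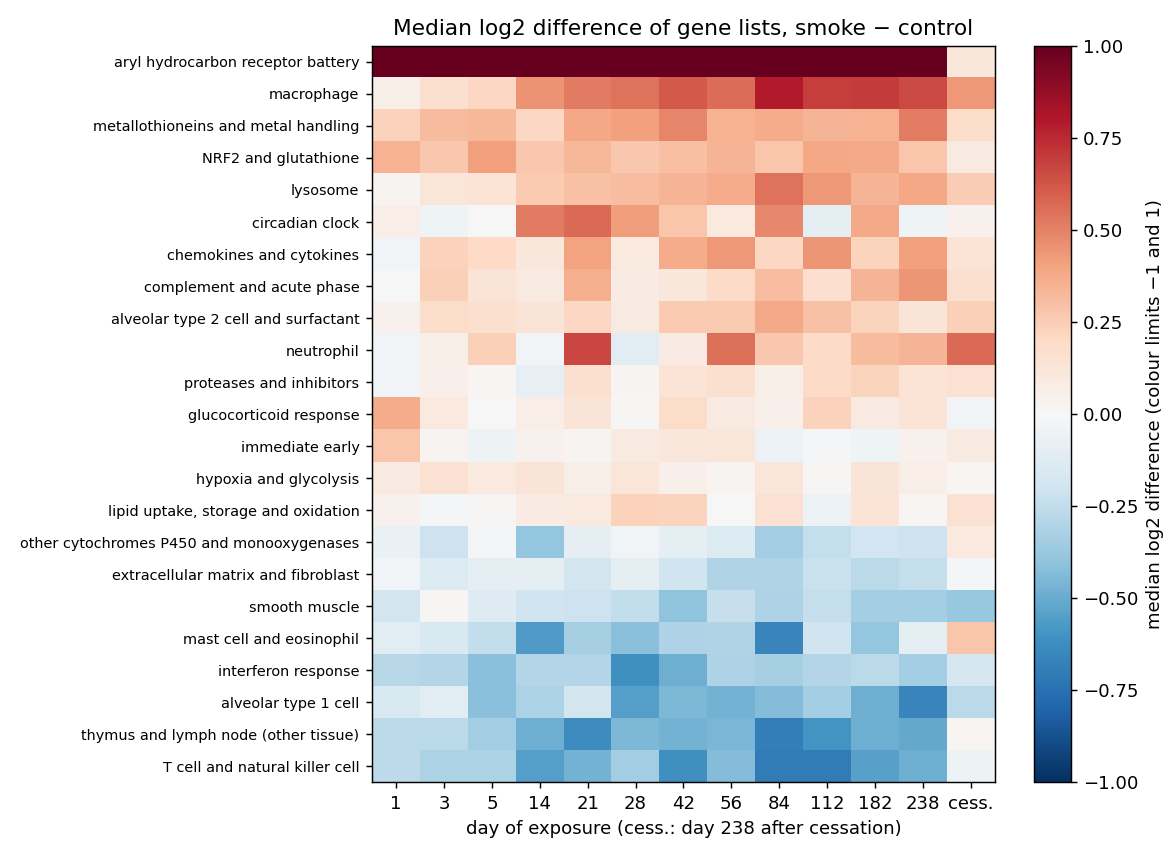
Median log2 difference between smoke and control groups (colour, limits at -1 and 1) of the 23 lists that passed on the average difference, by day of exposure and after cessation. The macrophage list had a median of 0.43 after cessation, the T and natural killer cell list -0.05, and the aryl hydrocarbon receptor battery exceeds the colour limit on every exposure day.

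The time course asked whether the response changed with the length of exposure. Ctsk, a collagen-degrading cathepsin, had the largest F at 24.4 (adjusted p = 7.5e-27): its difference was 0.27 ± 0.19 on day 1 and not called, 1.06 ± 0.20 on day 14, and 2.91 ± 0.19 on day 182. Ctsd followed with an F of 18.8, the arginase Arg1 with 15.1, Mmp12 with 12.7 and S100a9 with 12.3. Mmp12 stood at -0.03 ± 0.33 on day 1, 1.49 ± 0.34 on day 14, 3.11 ± 0.33 on day 42 and 3.79 ± 0.33 on day 238. On day 3 it was 0.97 ± 0.32 with an adjusted p of 0.049, and this call was lost with array weights at an adjusted p of 0.11, without the filter at 0.062 and with the larger constant at 0.073. Cyp1a1 and Nqo1 passed with an F of 3.4 and 3.3 (adjusted p = 0.0045 and 0.0059), and Scgb1a1 did not (adjusted p = 0.78). In all, 1098 probe sets for 641 genes passed the limma F test, and 1869 with array weights.

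The mean difference of days 112, 182 and 238 minus that of days 1, 3 and 5 gave the direction. Mmp12 rose further by 2.71 ± 0.27 (adjusted p = 7.1e-16), S100a9 by 2.41 ± 0.24, Ctsk by 2.28 ± 0.16, and S100a8 by 1.80 ± 0.31. Also rising further were the acute phase protein Orm1 by 1.70 ± 0.24, Ccl3 by 1.63 ± 0.17, Ceacam4 by 1.62 ± 0.19, Arg1 by 1.59 ± 0.16 and Pdzk1ip1 by 1.59 ± 0.30. Spp1 rose by 1.69 ± 0.43 with an adjusted p of 0.0024, and by 1.36 with an adjusted p of 0.066 when day 182 was left out. Cyp1a1 stood at 0.56 ± 0.15, but its control signal, near the constant added, fell by 0.43 ± 0.11 over the same days, so a growing effect on smoke lungs is not shown. Nqo1 stood at -0.50 ± 0.12, with controls that rose by 0.28 ± 0.08, and Aldh3a1 at -0.71 ± 0.13. Cdh22 fell by 2.19 ± 0.33 (adjusted p = 3.5e-08), Dlk1 by 1.58 ± 0.28, the calcium-binding protein Tesc by 1.19 ± 0.22, Nell1 by 0.94 ± 0.26, the lipoxygenase Alox15 by 0.85 ± 0.16 and Zp2 by 0.84 ± 0.23. The globins Hba-a3 and Hbg1 fell by 1.04 ± 0.31 and 0.81 ± 0.25, the troponin Tnnt3 by 1.04 ± 0.36 and Cyp2d3 by 0.81 ± 0.29. The last 3 calls were lost under at least 1 alternative, with an adjusted p of 0.059 for Hbg1 and 0.13 for Cyp2d3 without day 182, and 0.074 for Tnnt3 with arrays centred on the median. Scgb1a1 stood at -0.06 ± 0.07 and did not pass.

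Of 806 probe sets that passed, 339 were higher and 467 lower; with quantile normalization the numbers were 382 and 319, and with centring 451 and 164. The arrays of day 182 had the highest 3' over 5' log2 ratios of control probe sets, 1.32 ± 0.22 in controls and 1.22 ± 0.38 with smoke (SD) against means from 0.24 to 0.97 in the other groups. Without that day 424 passed, 219 higher and 205 lower. Of the 40 lists 10 passed, 8 of them also with an estimated correlation. The macrophage list had 15 of 21 members higher and 0 lower (adjusted p = 3.4e-27; 16 adjusted over the list alone), with Ctsk, Acp5 at 1.12 ± 0.11, Mmp12 and Ctsd. The lysosome list had 13 of 27 higher (adjusted p = 8.5e-24; 14 adjusted over the list alone) and 0 lower, and proteases and inhibitors 12 of 32 higher and 1 lower (adjusted p = 3.9e-08; 12 and 2 adjusted over the list alone). Complement and acute phase genes had 7 of 18 higher (8 adjusted over the list alone), chemokines and cytokines 6 of 23 higher and 2 lower (7 and 2), and neutrophil markers 3 of 9 higher (4). The adjusted p of these lists were 4.4e-05, 0.00062 and 2.2e-05. Antigen presentation genes had 7 of 20 higher and 1 lower, among them Ctss at 0.70 ± 0.09 and the class II genes RT1-Ba at 0.71 ± 0.15 and RT1-DMb at 0.53 ± 0.10 (adjusted p = 6.8e-05; 7 and 1 adjusted over the list alone). Alveolar type 2 genes had 4 of 16 higher, with Chia at 1.20 ± 0.18 (adjusted p = 5.8e-05; 5 higher and 1 lower adjusted over the list alone). Metal handling genes had 3 of 10 higher, with Slc11a2 at 0.64 ± 0.08 (3 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.084 with an estimated correlation). Markers of T and natural killer cells had 6 of 22 lower, among them Klrb1a at -0.59 ± 0.14 (7 adjusted over the list alone; adjusted p = 0.0057, and adjusted p = 0.37 with an estimated correlation). The NRF2 list did not pass (adjusted p = 0.57).

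The cessation groups asked which differences remained on day 238 once exposure had ended. Among the genes that remained higher was Mmp12, by 2.34 ± 0.33 (5.05-fold, adjusted p = 8.7e-08). Its mean signal was 136 ± 91.6 in the cessation smoke group against 18.8 ± 7.08 in its own controls (SD, n = 8 in each), and 7 of 8 smoke arrays lay above every control. Spp1 was higher by 2.26 ± 0.53 (adjusted p = 0.0041, 5 of 8 arrays above every control), Chia by 1.76 ± 0.22 (adjusted p = 1.3e-09, 7 of 8), S100a9 by 1.68 ± 0.29 (adjusted p = 2.7e-05, 6 of 8), Ctsk by 1.49 ± 0.19 (adjusted p = 1.9e-09, 8 of 8) and Orm1 by 1.47 ± 0.30 (adjusted p = 0.00051, 8 of 8). Also higher were the kininogen Kng2 by 1.38 ± 0.22, the potassium channel Kcnh4 by 1.27 ± 0.33. Less certain were the nitric oxide synthase Nos2, higher by 1.63 ± 0.50 (adjusted p = 0.044, and 0.076 with quantile normalization) and the matrix protein Chad by 1.27 ± 0.36 (adjusted p = 0.024, and 0.092 with quantile normalization). Lower were Cdh22 at -1.96 ± 0.40 (adjusted p = 0.00057, 7 of 8 arrays below every control), the potassium channel Kcnd3 at -1.54 ± 0.36, Dlk1 at -1.35 ± 0.34, the growth factor Fgf18 at -1.22 ± 0.33 and Tesc at -0.88 ± 0.27 (adjusted p = 0.044, and 0.056 without the filter). The detoxifying genes did not pass: Cyp1a1 stood at 0.39 ± 0.19 (adjusted p = 0.23) with a mean signal of 2.74 ± 0.863 against 1.49 ± 0.376. All 8 arrays lay above the control mean for Cyp1a1, and its adjusted p was 0.024 with the cessation groups alone in the fit. Nqo1 stood at 0.28 ± 0.15 (adjusted p = 0.28) and Scgb1a1 at -0.08 ± 0.08 (adjusted p = 0.58).

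After cessation 221 probe sets passed, 147 higher and 74 lower. The cessation smoke arrays had a median signal of 42.4 ± 3.51 against 37.7 ± 0.712 in their controls (SD), and the scaling mattered: quantile normalization gave 117 higher and 92 lower and centring 72 and 303, moving the median of all probe sets from 0.0474 to -0.108. The count was 375 with centring, 741 with the cessation groups alone, 969 with array weights and 423 with replicate number as a block. Of 40 lists 13 passed, 8 higher and 5 lower, and 6 also did so with an estimated correlation. The macrophage list had 9 of 21 members higher and 0 lower, with Acp5 at 0.83 ± 0.13 (adjusted p = 1.5e-10; 14 adjusted over the list alone). The lysosome list had 8 of 27 higher and 0 lower (adjusted p = 3.8e-07; 13 adjusted over the list alone), and proteases and inhibitors 9 of 32 higher and 0 lower (adjusted p = 0.00084; 11 adjusted over the list alone). Centring lowered the medians of all 13 lists, from 0.43 to 0.28 for the macrophage, from 0.25 to 0.09 for the lysosome and from 0.15 to -0.00 for the protease list. The neutrophil list had 2 of 9 higher, S100a9 and Cxcr1 (adjusted p = 0.00028; 4 adjusted over the list alone). Smooth muscle genes had 2 of 13 lower, Actg2 at -0.81 ± 0.15 and Tagln at -0.64 ± 0.13 (adjusted p = 3.9e-06; 6 adjusted over the list alone). Alveolar type 1 markers had 1 of 9 lower, Igfbp2 at -0.74 ± 0.17 (adjusted p = 0.0015; 1 adjusted over the list alone).

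The other 7 lists lost their call after cessation when the correlation was estimated. Chemokines and cytokines had 5 of 23 members higher and 1 lower (7 and 2 adjusted over the list alone; adjusted p = 0.035, and adjusted p = 0.18 with an estimated correlation), and their median of 0.14 became -0.01 with centring. Complement had 3 of 18 higher (5 adjusted over the list alone; adjusted p = 0.04, and adjusted p = 0.18 with an estimated correlation), with C1qb at 0.49 ± 0.12, and their median of 0.16 became 0.01 with centring. Alveolar type 2 genes had 2 of 16 higher, Chia and Ctsh (5 adjusted over the list alone; adjusted p = 0.03, and adjusted p = 0.16 with an estimated correlation). Their median of 0.24 became 0.08 with centring. The calls of the alveolar type 2, complement, mesothelium and interferon lists were also lost with centring. Mesothelium had 1 of 6 higher, C3, and 2 lower, the keratins Krt8 and Krt19 (1 and 3 adjusted over the list alone; adjusted p = 0.04, and adjusted p = 0.16 with an estimated correlation). Interferon response genes had 0 of 15 called (0 adjusted over the list alone; adjusted p = 0.035, and adjusted p = 0.47 with an estimated correlation), with a median of -0.17 that became -0.32 with centring. Ribosomal proteins had 0 of 37 called (0 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.45 with an estimated correlation), with a median of -0.08 that became -0.23 with centring and -0.04 with quantile normalization. Fat genes had 0 of 10 called (4 adjusted over the list alone; adjusted p = 0.0069, and adjusted p = 0.34 with an estimated correlation), with a median of 0.52. No member of the aryl hydrocarbon receptor battery, the NRF2 list or the T and natural killer cell list passed (0 of 6, 0 of 28 and 0 of 22), also adjusted over the list alone. By limma 1190 of all probe sets had an unadjusted p under 0.05.

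Whether the difference after cessation was smaller than under continuing exposure was tested directly. Cyp1a1 stood at -7.71 ± 0.27 (adjusted p = 6.2e-67), Cyp1b1 at -4.48 ± 0.34, Aldh3a1 at -3.71 ± 0.23, Ggt1 at -2.78 ± 0.35 and Nqo1 at -1.23 ± 0.21 (adjusted p = 5.9e-06), so the effect of smoke on each was smaller after cessation. Pdzk1ip1 stood at -1.82 ± 0.53 (adjusted p = 0.041, and 0.053 with the groups of day 238 alone). The most positive were Tac1 at 1.26 ± 0.29, the kallikrein Klk6 at 1.20 ± 0.31, the peptide transporter Slc15a2 at 1.12 ± 0.27, Akr1c14 at 1.08 ± 0.21 and the receptor Kit at 1.07 ± 0.30. With quantile normalization Klk6 had an adjusted p of 0.062 and Kit lost its call at 0.05, and Slc15a2 had one of 0.055 with centring. Mmp12 stood at -1.45 ± 0.47 and did not pass (adjusted p = 0.077). It passed with quantile normalization (adjusted p = 0.047), with centring (adjusted p = 0.039) and with array weights (adjusted p = 0.014). Scgb1a1 stood at 0.08 ± 0.12 (adjusted p = 0.81). In all 127 probe sets passed, 51 higher and 76 lower, against 32 and 92 with quantile normalization and 25 and 144 with centring, which moved the median of all probe sets from 0.1 to -0.0922. The count was 350 with the groups of day 238 alone and 481 with array weights.

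Of 77 genes higher after cessation, 41 were also higher on day 238 under continuing exposure, where 4.92 would overlap by chance. Of 50 lower genes 32 were also lower, where 6.01 would overlap by chance. The pairs of groups had separate controls. The 1118 genes that differed on day 182, chosen in other animals, were then followed. Signed by their direction on day 182, their median log2 difference on day 238 was 0.271 under continuing exposure (95% interval from resampled animals 0.227 to 0.336) and 0.073 after cessation (0.018 to 0.118). The difference of -0.199 had an interval from -0.277 to -0.129. The median after cessation was 0.112 with quantile normalization and 0.089 with centring, the latter added after seeing the data, and the differences from continuing exposure were -0.190 and -0.223. Of the 1118 genes 924 kept their sign under continuing exposure and 681 after cessation, and 429 and 63 were called in the same direction, 56 of them in both. Only 60 of the 1118 were called in the test of cessation against continuing exposure itself.

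**Figure D4:**
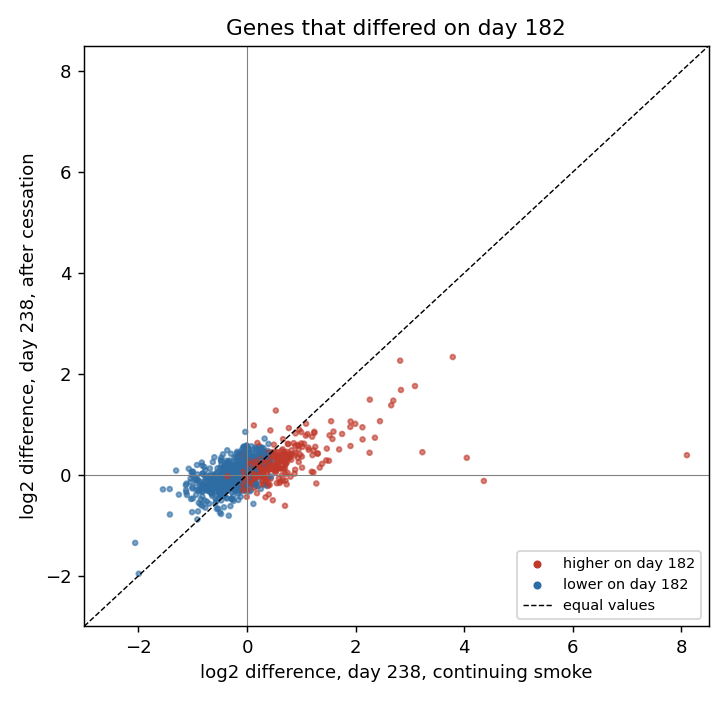
Log2 difference on day 238 under continuing smoke (horizontal axis) and after cessation (vertical axis) for the 1118 genes that differed on day 182, as red points for the 311 higher and blue points for the 807 lower on that day, with a dashed line of equal values. Cyp1a1 lies at 8.10 and 0.39, and Mmp12 at 3.79 and 2.34.

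The control groups gave the background. Between the controls of the cessation groups and the other controls of day 238, Cyp1a1 stood at -0.10 ± 0.19, Nqo1 at -0.21 ± 0.15, Scgb1a1 at -0.10 ± 0.08 and Mmp12 at 0.43 ± 0.33, and none passed. By limma 1 probe set, which stands for no gene here, passed the adjusted threshold and 714 had an unadjusted p under 0.05. The count depended on the fit: 132 passed with these groups alone, 43 higher and 89 lower, and 470 with array weights.

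The controls of days 112, 182 and 238 against those of days 1, 3 and 5 showed how unexposed lungs differed over the course, which includes age. Genes of the extracellular matrix fell: elastin (Eln) stood at -1.85 ± 0.12 (adjusted p = 2e-30), the microfibril protein Ltbp2 at -1.79 ± 0.16, and the collagens Col3a1 at -1.57 ± 0.07, Col1a2 at -1.37 ± 0.06 and Col15a1 at -1.32 ± 0.10. The activin inhibitor Fst stood at -1.63 ± 0.15, Hsd11b2 at -1.36 ± 0.16 and the clock repressor Nr1d1 at -1.36 ± 0.19. The chaperone Hspa1a rose by 1.76 ± 0.19 (adjusted p = 1.9e-14), the endothelial gene Esm1 by 1.48 ± 0.16, and the transcription factors Nr4a1 and Klf4 by 1.37 ± 0.14 and 1.11 ± 0.08. Also higher in late controls were the kinase Prkce by 1.21 ± 0.07, Kcnk5 by 1.17 ± 0.23, Fbp1 by 1.12 ± 0.22 and albumin (Alb) by 1.27 ± 0.48 (adjusted p = 0.028). Cyp1a1 fell by 0.43 ± 0.11 (adjusted p = 0.0006), Nqo1 rose by 0.28 ± 0.08 (adjusted p = 0.0056) with 1 other probe set of Nqo1 called lower, Scgb1a1 rose by 0.12 ± 0.05 (adjusted p = 0.031), and Mmp12 stood at -0.32 ± 0.19 (adjusted p = 0.19). Without day 182 the adjusted p was 0.079 for Nqo1 and 0.25 for Scgb1a1, and with the 3' over 5' ratio as a covariate 0.14 for Scgb1a1. With only the groups of the comparison Mmp12 passed at 0.025 and Scgb1a1 did not.

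Among these controls 2162 probe sets passed, 1033 higher and 1129 lower, or 1383 and 768 with arrays centred on the median, and 1322 passed without day 182. The 3' over 5' log2 ratio averaged 1.32 in the controls of day 182 against 0.60, 0.67 and 0.56 on days 1, 3 and 5, and this comparison does not cancel RNA quality. Of the 2162 calls 1794 were kept in direction with the ratio as a covariate and 1067 without day 182. Of 40 lists 7 passed, and 5 also with an estimated correlation. All 7 also passed in the same direction with the ratio as a covariate and without day 182. Of 38 extracellular matrix genes 27 fell and 4 rose (adjusted p = 2.3e-16), and of 13 smooth muscle genes 11 fell and 1 rose (adjusted p = 6.7e-05). Heat shock genes had 17 of 25 higher and 1 lower (adjusted p = 3.6e-08; 18 and 1 adjusted over the list alone), immediate early genes 15 of 27 higher and 4 lower (adjusted p = 3.6e-08; 16 and 4 adjusted over the list alone), and glucocorticoid response genes 10 of 19 higher and 1 lower (adjusted p = 0.0028). Cell cycle genes had 14 of 24 lower and 0 higher (15 adjusted over the list alone; adjusted p = 0.00042, and adjusted p = 0.081 with an estimated correlation). Red blood cell genes had 4 of 7 lower and 1 higher (5 and 1 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.081 with an estimated correlation). Adjusted over the list alone, the counts of the matrix, smooth muscle and glucocorticoid lists were unchanged.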

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

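The tests on macrophage genes after cessation and those on splits for the gene lists were chosen only after the result was seen. With 6 measures in each of 26 groups, 156 sets of arrays were examined for an array far from the others. Of these 21 (13.5%) had one, where chance gives about 1 in 20 groups.

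Cyp1a1 was far above the other controls on 1 control array each of day 14 (4.66 in log2, nearest 3.04), day 42 (4.31, nearest 2.58) and day 5 (4.19, nearest 2.74), and far below the other smoke arrays on 1 of day 56 (9.49, nearest 10.29). Nqo1 was lowest on 1 smoke array of day 1 (9.90, nearest 10.80) and highest on 1 of day 28 (10.93, nearest 10.50). Scgb1a1 was lowest on 1 smoke array of day 182 (10.36, nearest 10.61), 1 control array of day 3 (9.71, nearest 10.58) and 1 smoke array of day 42 (10.23, nearest 10.62), and highest on 1 smoke array of day 3 (10.70, nearest 10.51). Mmp12 was highest on 1 smoke array of day 14 (6.83, nearest 5.92) and lowest on 1 control array of day 238 (3.19, nearest 3.80) and 1 smoke array of day 3 (4.55, nearest 5.34). The median signal stood apart on 1 smoke array of day 112 (40.30, nearest 38.60), 1 control array of day 238 (45.00, nearest 40.10) and 1 control array of day 5 (33.90, nearest 40.10). The 3' over 5' log2 ratio stood apart on 1 smoke array of day 182 (2.13, nearest 1.33), 1 control array of day 21 (2.85, nearest 1.25), 1 control array of day 3 (1.16, nearest 0.72), 1 smoke array of day 3 (1.43, nearest 0.57) and 1 control array of day 5 (1.16, nearest 0.66). The arrays of days 3 and 5 named here for the ratio or the median signal all carry replicate number 3.

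Effects that differed between groups by a test of the difference itself were those of smoke across days (1098 probe sets), late against early (806) and after cessation against continuing exposure (127).

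More probe sets were lower than higher in smoke lungs on days 84, 112 and 182. The median signal of the arrays differed as well, with 41.1 ± 2.03 in smoke arrays against 47.3 ± 1.03 in controls on day 84 (SD). It was 38.4 ± 0.893 against 43.2 ± 2.24 on day 112 and 34.5 ± 3.38 against 37.9 ± 2.38 on day 182. The day 84 controls had the highest value of the 26 groups, so the difference there need not lie in the smoke arrays. A wrong scaling factor per array would move all probe sets alike, but the median difference of the brightest of 4 equal parts lay 0.187 above that of the dimmest, which argues against it as the whole cause. A candidate explanation for part of it is the signal of dim probe sets near background: from dimmest to brightest the 4 parts had medians of -0.217, -0.199, -0.133 and -0.030 over the 3 days. The calls were not concentrated there: 266 were lower and 44 higher in the dimmest part on day 84 against 266 and 275 in the brightest, but on day 182, where the dimmest median (-0.153) was above the next (-0.181), 177 and 80 against 315 and 220. The arrays had been scaled to a trimmed mean between 150.1 and 150.3, far above their median signals, so bright probe sets weigh most in it. That scaling tends to hold the brightest part near 0. Only the gap between the parts is therefore informative, and whether dim probe sets fell or bright ones rose cannot be told from it. A true fall of weakly expressed genes stays open.

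Muscle genes were lower in smoke than in control arrays on day 21. Heart or vessel muscle in a few control samples is a candidate explanation: 12 of 19 measured heart muscle genes had their highest control value on array 7, and the other 7 on array 5. Of the 19 genes 3 also stand in another list, and the brightest over all arrays was Actc1 with a mean of 9.15. For an effect of smoke, the rule set before this test asked for at least 7 of 8 control arrays above the highest smoke array (7.07), by the mean over the list. At most 4 of 8 was to count against it, and 4 were found. By that rule the result counts against an effect of smoke, though with a value on the bound. Smoke arrays themselves ranged from 4.28 to 7.07, and a smaller effect of smoke beside muscle in the samples cannot be told apart.

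Macrophage genes remained higher after cessation, and arrays of continuing exposure among the cessation arrays are argued against, since 0 cessation smoke arrays had a Cyp1a1 signal as high as the lowest array of continuing exposure. More macrophages in the tissue cannot be told apart from a change per cell: the median difference of the list without Mmp12 was 0.416, with 17 of 20 members above 0, but this restates the result and either would give it. The fat list also had a median of 0.52 (adjusted p = 0.0069 by camera, and 0.34 with an estimated correlation). It shares Fabp4, at 1.94 ± 0.80, and Lpl with the macrophage list, though none of the 8 called genes among the 20 is in the fat list. Yet Lyz2, the brightest member with a mean of 12.80, stood at -0.19 ± 0.12, and Csf1r at 0.02 ± 0.24, Cd14 at 0.10 ± 0.17 and Ctsl at -0.17 ± 0.08, and 15 of the 21 measured genes stand in other lists.

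For each comparison 100 splits of the same arrays were drawn, the real one included. On each of the 12 days only 1 split, the real one, gave as many probe sets, so chance is an unlikely source of these counts. It is not excluded, since 1 of 100 is the smallest share the test can give. The other splits also mixed smoke and control arrays on all days at once, which can widen the shared spread and lower their counts. The highest other splits gave 18 on day 1 (real 279), 93 on day 3 (408), 14 on day 5 (313), 13 on day 14 (519), 577 on day 21 (789), 50 on day 28 (667), 2 on day 42 (715), 72 on day 56 (1152), 5 on day 84 (1803), 308 on day 112 (1477), 106 on day 182 (1821) and 19 on day 238 (1049). The 577 of day 21 came near the real count, and its source was not tested. Without the 4 arrays of low correlation, 529 of the 789 calls of day 21 were kept. A control array of day 21 was among these arrays, with the lowest median correlation (0.8328) and a 3' over 5' log2 ratio of 2.85. With that ratio as a covariate 618 were kept, and with array weights 463, so part of the day 21 count depended on array quality. The real split was also the only 1 of 100 for the average (real 3430, highest other 16) and after cessation (221, 0). It was likewise the only 1 for the F test (1098, 11) and for late minus early (806, 26). The other splits mixed smoke and control arrays within each day, which takes away the effect of smoke on every day. For the F test and late minus early they therefore cannot tell whether chance gave a change of that effect between days. For the controls over time the real split was also the only 1 of 100 (2162, 458). Those splits moved single arrays between days, so differences between days of another source, such as processing, are not excluded.

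For cessation minus continuing exposure 3 of 100 splits gave at least the real 127. The highest other split of that comparison gave 362. These splits mixed smoke and control lungs of all groups of day 238, which carried the effect of smoke itself into the contrast. They therefore cannot tell whether chance gave the 127. For the controls of day 238 chance cannot be excluded: 8 of 100 splits gave at least the real 1, and the highest other 9. For the number of gene lists the real split was the only 1 of 100 for the average (real 23, highest other 19, median of the others 4). The 19 came near the real count, so chance is less likely there but not excluded. Chance cannot be excluded for late minus early (14 of 100, real 10, highest other 19), after cessation (6 of 100, real 13, highest other 16) or the controls over time (21 of 100, real 7, highest other 11). List by list, a test added after seeing the data, fewer than 5 of 100 splits gave as small a p for 17 of 23, 8 of 10, 6 of 13 and 4 of 7 called lists. After cessation those 6 were the macrophage, lysosome, protease, neutrophil, alveolar type 1 and smooth muscle lists.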

How the results depend on the processing

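Leaving out 4 arrays of low correlation, day 182 or day 21, and centring for gene lists and persistence, were tests added only after the result was seen. Where a count changed by over 1.5 times the cause was not tested. With only the groups of the comparison 241 probe sets passed on day 3, 186 on day 5, 251 on day 21, 434 on day 28, 741 after cessation, 350 for cessation minus continuing exposure and 132 for the controls of day 238. With array weights 510 passed on day 21, 1696 on day 238, 1869 in the F test, 969 after cessation, 481 for cessation minus continuing exposure and 470 for the controls of day 238. With centring on the median 375 passed after cessation. Correlations of equally numbered arrays averaged 0.27 on day 5, with a lowest pair of 0.10, and 0.20 on days 1 and 28. On days 1, 3 and 5 the arrays numbered 3 had the lowest median signal of their control and smoke groups, between 32.9 and 36.2. Their 3' over 5' log2 ratios were 0.82 and 1.43, 1.16 and 1.43, and 1.16 and 1.15 (control and smoke). Arrays numbered 3 thus shared a property on those days, of a source that the labels do not give. Low median signals with high ratios also occurred on days 14, 21 and 28, under numbers 2 and 3, though not on every array so numbered. Examples are smoke array 2 of day 14 (32.9 and 0.97), smoke array 2 of day 21 (33.2 and 0.91) and control array 3 of day 28 (32.1 and 1.34). The property was therefore not limited to number 3 or to days 1, 3 and 5. Whether all numbers mark pairs stays open on days 1, 5 and 28. With replicate number as a block 423 passed after cessation and 7 for the controls of day 238. Those controls, with 1 probe set in the fit reported, also gave 2 with quantile normalization, 0 with the smaller constant, 0 without the filter, 0 with the RNA quality covariate and 6 without the 4 arrays. Without day 182, 424 passed for late minus early, 1322 for the controls over time, and 11 gene lists for those controls. With an estimated correlation 14 lists passed on the average and 6 after cessation. The persistence difference of -0.199 stayed between -0.272 and -0.179 in all alternatives, at -0.223 with centring. Its median after cessation moved from 0.073 to 0.112 with quantile normalization.

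Among named genes 2520 values kept their direction and call, 37 lost the call, 7 gained it and 9 changed sign. The changes of sign were of genes that did not pass: Scgb1a1 became 0.01 on day 1 with quantile normalization, 0.00 on day 21 with array weights, 0.01 with the RNA quality covariate and 0.04 without the 4 arrays. With centring Scgb1a1 became 0.16 on day 84, 0.14 on day 112, 0.02 for late minus early and -0.12 for cessation minus continuing exposure. Cyp1a1 became 0.02 between the controls of day 238 with quantile normalization. The cause was not tested. Signal over background limits what dim probe sets can show, and Cyp1a1 in controls lies near the constant added.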

Other observations

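This part holds no test, so none was chosen after the result was seen. For the array whose labels conflict between control and smoke on day 14, signals of named genes were set beside the 7 control and 8 smoke arrays of that day. Cyp1a1 was 2.3 on this array, between 1.4 and 22.8 in controls and between 755 and 1313 with smoke. Cyp1b1 was 61.1, between 33.9 and 71.8 in controls and between 595.8 and 1415.7 with smoke. Nqo1 was 344.1, between 287 and 462.1 in controls and between 903.8 and 2127.9 with smoke. Mmp12 was 17.7, between 8.9 and 23.2 in controls and between 32.8 and 111.6 with smoke. Aldh3a1 was 8.9, under the 37.5 to 79.3 of the controls and the 943.8 to 1649.9 of the smoke arrays. Scgb1a1 was 1727.6, within the controls (1472 to 1958.8) and the smoke arrays (1336.9 to 1789.7).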
